A study of Oryzias latipes with 4 samples.

How the data were processed

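The series measured messenger RNA in the brain of female medaka (Oryzias latipes), a small freshwater teleost whose reproduction follows day length. Per the labels, fish kept under short days (SD) either stayed there or were moved to long days (LD), and tissue was collected 16 h after the transition. The dissected block held the ventral telencephalon, the hypothalamus and the pituitary, from 6 fish per condition. There were 2 libraries per group, named here SD 1, SD 2, LD 1 and LD 2. How the 6 fish map to the 2 libraries is not stated in the labels, so p-values measure the spread between these libraries, which may be partly technical.

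Stranded mRNA libraries were made with a TruSeq kit, per the labels' protocols. HISAT2 2.0.5 and StringTie 1.3.3b are named in the submitters' processing notes, which give no roles or settings. The authors deposited 1 table of FPKM (fragments per kilobase of feature, scaled to the mapped total), with 1 FPKM column per library per the file headers. The table holds 93896 features, each with a locus, a length and the best BLAST hit. The genome build is not given in the sources used here, and coordinates in the text are those of the deposited table. Of the lengths, 79.0% are multiples of 3, so many features may be coding-length models. Whether they lack untranslated regions was not tested.

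A feature was given its hit's gene name where the hit's own location overlapped the feature. This held for 46410 of the 52142 features with a hit (89.0%), and 41754 features had no hit. All 20707 gene identifiers were found in the RefSeq gene table of assembly ASM223467v1, which was used for names only. FPKM values of features that share a gene identifier were summed, and features without a name were kept as units of their own, for 68193 units in all. Summing cannot separate reads that near-identical paralogs share.

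FPKM values are not counts, so no count test was used. Relative depth was read from the most frequent small product of FPKM and length, taken as the worth of 1 read. Between 2.4% and 6.6% of the values above 0 in a library lay below that worth, so counts were not rebuilt and no counting interval is given. On that scale SD 2 was the shallowest library (1.0), SD 1 had 1.36 times its depth, and LD 1 and LD 2 each had 1.49 times. The share of 6.6% was that of SD 2, against 2.4% in each other library. SD 2 also had the most features above 0 (39789, against 37506 to 37823), so its depth on this scale is uncertain. The sum of FPKM was 458696.5 in SD 1, 463065.7 in SD 2, 461076.0 in LD 1 and 460120.5 in LD 2. None of the 69 ribosomal protein genes with a mean FPKM of at least 1 was at 0 in any library, but 10 features were at 0 in 1 library and at 10 FPKM or more in another. A value of 0 is therefore given as listed at 0, with no fold.

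Genes and features with a mean of at least 1 FPKM over the 4 libraries (17252, of which 15297 carried a gene name) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The fit used group as its only term, empirical Bayes moderation with a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment, with 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists (26) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A second adjustment was made over each list alone and over the key genes alone. Tables were read with Python 3.11.15 and pandas 2.3.3, t quantiles came from scipy 1.17.1, exact permutations were enumerated in Python, and plots were drawn with matplotlib 3.10.9.

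The design, the lists, the key genes and the alternatives listed in advance were fixed before the data were examined. Named genes were chosen by rule, largest fold first, among those past the threshold with both LD libraries on the same side of both SD libraries. Where fewer than 8 per direction passed, places up to 8 went to the smallest unadjusted p, with at most 3 bare locus names or unnamed features per direction. Key genes were named whatever their result. From each list, members past the threshold over the list alone were named (at most 4), or the 2 members with the highest mean FPKM where there were none. Other genes are said to have been chosen after their values were seen. Description matches for lists caught some unrelated genes, such as transducin-like enhancer proteins among the phototransduction genes. The lists were kept as fixed, and a run without those members was added later. Key entries gnrh1, per3 and dbp had no match and were not analysed here.

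The fit was tested on simulated data made from the means of the 17252 genes. At a 2-fold change 74.6% of the changed genes were called, at 4-fold 91.0% and at 8-fold 93.9%, with 7 false calls among 180. Changes were planted in 67, 67 and 66 genes, with independent noise drawn from the variances of the fit. The 180 calls eased the adjusted threshold, so these shares do not give the power in the real data. Alternatives tried were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, the replicate number as a block, leaving out each library in turn, limma without trend or with robust variance, and the features as deposited without summing.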

Results

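RNA from the ventral telencephalon, hypothalamus and pituitary of female medaka was compared between fish kept under short days (SD) and fish moved to long days (LD) 16 h before collection. The comparison asks which genes differ at the end of that first interval under the longer day. Each group had 2 libraries, from 6 fish per condition. Between 22556 and 22869 features reached 1 FPKM in a library. Pearson correlations of log2(FPKM + 1) across genes were 0.980 between the SD libraries, 0.981 between the LD libraries and 0.977 to 0.982 between groups. The median absolute difference in log2(FPKM + 1) was 0.126 between the SD libraries, 0.118 between the LD libraries and 0.121 to 0.135 between groups. By both measures the ranges within and between groups overlap, and genes are not independent replicates.

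Somatotropin, the growth hormone made by the pituitary, fell after the transfer from 889.9 ± 33.4 FPKM in SD to 268 ± 7.5 in LD (SD of the values, n = 2 libraries each), a 3.31-fold lower level. An unnamed feature, MEDAKA053081, was listed at 0 in both SD libraries and at 12 and 9.64 FPKM in LD 1 and LD 2. These were the only 2 of 17252 genes and features past the threshold, 1 higher and 1 lower in LD (limma adjusted p = 0.0338 for MEDAKA053081 and 0.0248 for somatotropin). The somatotropin gene (LOC101171460) lies on chromosome 8 at 73228 to 76797 on the plus strand, with 6 coding segments, and its log2 fold change was -1.73 with a standard error of 0.07. MEDAKA053081 lies on chromosome 4 at 31549591 to 31551946. It was given no gene name, overlaps another unnamed feature and is 17732 bp from the nearest named gene, which encodes a collagen alpha-1(XXVII) chain-like protein. At an unadjusted p under 0.05 there were 1091 genes, 438 higher and 653 lower, where 863 are expected by chance. The libraries of the 2 groups did not overlap for 37.1% of genes, and chance gives 33.3%. Neither call was kept when any 1 library was left out. Such a fit has fewer residual degrees of freedom, so a call can be lost with little change in the values. The log2 fold change then lay between -1.76 and -1.69 for somatotropin and between 3.41 and 3.70 for MEDAKA053081. Both calls were also lost with the replicate number as a block (0.213 for somatotropin and 0.221 for MEDAKA053081) and with no filter (0.439 for each), that of somatotropin with limma run without a trend (0.0571), and that of MEDAKA053081 with a pseudocount of 0.1 (0.104).

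**Figure D1:**
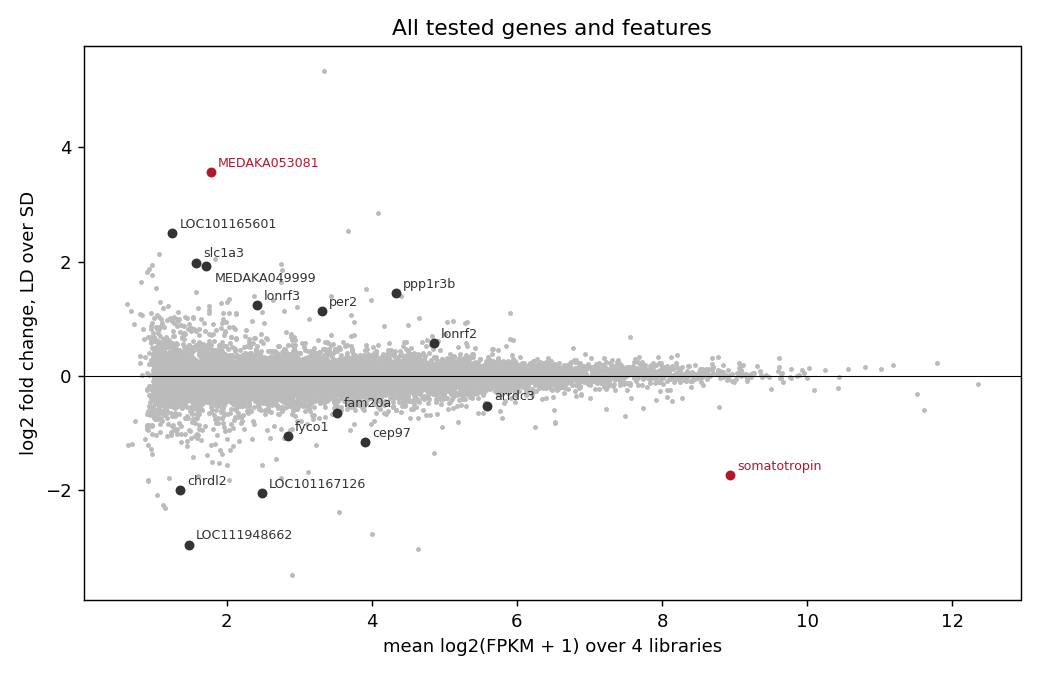
Log2 fold change of LD over SD (y axis) against mean log2(FPKM + 1) over the 4 libraries (x axis) for the 17252 genes and features tested, with the genes chosen by rule labelled and the 2 past the threshold in red. Somatotropin lies apart from other abundant genes at -1.73.

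Among the genes next in rank, which did not pass the threshold over all genes, ppp1r3b had the smallest p of the higher ones. It encodes a subunit that directs protein phosphatase 1 to glycogen, and it stood at 11.2 ± 0.403 FPKM in SD and 32.3 ± 2.84 in LD (n = 2 each, limma adjusted p = 0.0851). The unnamed feature MEDAKA049999 begins 59 bp from ppp1r3b on chromosome 12 and stood at 0.678 ± 0.0424 and 5.4 ± 0.618 FPKM. The glutamate transporter gene slc1a3 was at 0.504 ± 0.0192 FPKM in SD and 4.93 ± 0.13 in LD. Its feature spans chromosome 12 from 27216078 to 27223208. Both lonrf3 (2.47 ± 0.293 and 7.19 ± 0.357) and lonrf2 (22.8 ± 1.04 and 34.4 ± 1.83), which encode proteins with a LON domain and a RING finger, had higher values in LD. The uncharacterized gene LOC101165601 was listed at 0 in both SD libraries and at 4.03 and 5.39 FPKM in LD.

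Of the lower ones, LOC111948662, a zinc finger protein gene, stood at 7.11 and 6.35 FPKM in SD and was listed at 0 in both LD libraries (limma adjusted p = 0.0513). The arrestin domain gene arrdc3 was at 56.3 ± 0.821 FPKM in SD and 39 ± 1.51 in LD, and a second gene of the same description, LOC101167126, at 10.5 ± 2.15 and 1.76 ± 0.109. The centrosomal gene cep97 stood at 21.4 ± 1.06 and 9.05 ± 0.247 FPKM and chrdl2, a chordin-like gene, at 4.15 ± 0.618 and 0.28 ± 0.059. The autophagy adaptor gene fyco1 was at 9.33 ± 0.26 and 4 ± 0.382, and the pseudokinase gene fam20a at 13.3 ± 0.58 and 8.17 ± 0.213. For slc1a3 and these 6 lower genes the limma adjusted p lay between 0.114 and 0.442. With limma run without a trend, slc1a3 (adjusted p = 0.0449) and LOC111948662 (0.0443) passed, and LOC111948662 passed too with robust variance (0.0418) and with features not summed (0.0295).

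The pituitary hormone list shifted down, with 14 of 20 tested genes lower in LD, a median log2 change of -0.18 and camera adjusted p = 0.00115 (adjusted p = 0.75 with an estimated correlation). Besides hormones, the list holds other genes, such as pou1f1, scg3, pcsk2 and drd2, and it lacks prolactin-1, given below. Adjusted over the list alone, 2 genes fell and none rose: somatotropin (limma adjusted p = 2.87e-05) and tshb (LOC105354380), the beta subunit of thyrotropin, the hormone that drives the thyroid. This tshb gene, on chromosome 7 at 13715953 to 13723437, fell from 16.4 and 34.5 FPKM in the SD libraries to 1.15 and 1.3 in LD (limma adjusted p = 0.00153 over the list and 0.188 over all genes). A second gene described as thyrotropin beta-like (LOC101171658) varied within SD more than between groups, at 52.7 and 281 FPKM in SD and 64.1 and 72.9 in LD. Somatolactin, a hormone of the growth hormone family known from fish, stood at 122 ± 26.4 FPKM in SD and 69.2 ± 12.1 in LD (limma adjusted p = 0.0519 over the list). Values for pomc were 1477 ± 145 and 1274 ± 155 FPKM, and for the shared alpha subunit cga 347 and 816 in SD against 393 and 339 in LD. Those for lhb were 111 ± 15.4 and 76.1 ± 31.3, and for fshb 10.4 ± 3.19 and 9.16 ± 0.267. The gene with the symbol prl was near the filter, at 1.91, 0.0648, 3.36 and 0.842 FPKM in SD 1, SD 2, LD 1 and LD 2. The transcription factor gene pou1f1, needed by the cells that make growth hormone, prolactin and thyrotropin, stood at 29.1 and 46.2 FPKM in SD and 21.6 and 23.8 in LD (limma adjusted p = 0.141 over the list), a gene chosen after its values were seen. Without SD 2 the list was no longer called (median -0.04, camera adjusted p = 0.252), and the log2 change was 0.07 for cga, 0.14 for fshb and 0.37 for the second tshb.

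**Figure D2:**
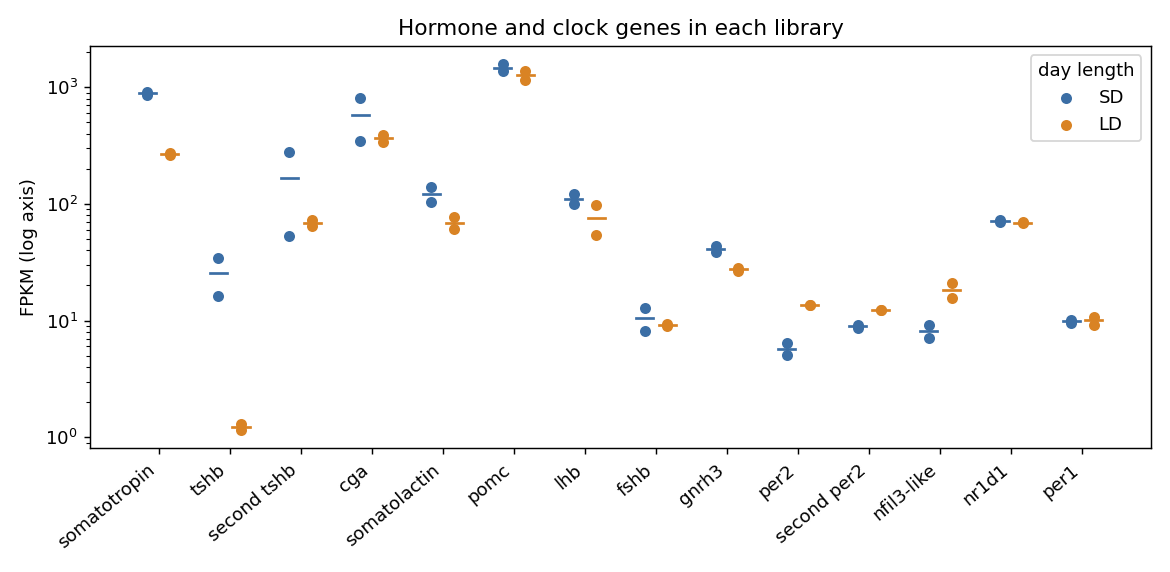
FPKM on a log axis for 14 hormone and clock genes, with 1 point per library (2 SD in blue, 2 LD in orange) and a bar at the mean of each group. Somatotropin, tshb and gnrh3 lie lower in both LD libraries and per2 higher in both, while nr1d1 and per1 lie close together.

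Marker genes of pituitary cells went both ways. Adjusted over that list alone, pitx1, a transcription factor gene of the pituitary, fell from 9.97 ± 1.17 to 6.15 ± 0.363 FPKM, and gata2, a transcription factor gene used by thyrotrophs and other cells, rose from 1.17 ± 0.0944 to 2.76 ± 0.134 (limma adjusted p = 0.0196 for both over the list). Neither was kept in the fit without LD 1, without LD 2, without SD 2 or without the expression filter. The list of 10 genes as a whole had a median of -0.39 and was not called (camera adjusted p = 0.307). Without SD 1 its median was -0.66 (camera adjusted p = 0.000973), and among genes with a mean of at least 5 FPKM it was -0.54 (0.0171), against adjusted p = 0.75 with an estimated correlation and all 4 libraries. The shift rests on SD 2. The median difference from SD 2 was -0.63 for LD 1 and -0.55 for LD 2. From SD 1 it was 0.09 and -0.03, and SD 2 minus SD 1 was 0.43. The hormone list also holds 5 of its genes, pou1f1, cga, lhb, fshb and prl.

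In the photoperiodic thyroid signalling list, the same tshb gene was the only one of 18 tested to pass over the list alone (limma adjusted p = 0.00275). With 13 genes lower and 5 higher and a median of -0.08, the list was not called (camera adjusted p = 0.273). Its median was -0.22 without SD 1 (camera adjusted p = 0.00027) and 0.09 without SD 2 (0.797), against adjusted p = 0.75 with an estimated correlation and all 4 libraries. Of the enzymes that activate and inactivate thyroid hormone, dio2 stood at 2.58 ± 0.819 FPKM in SD and 1.5 ± 0.318 in LD, and dio3 at 6.24 ± 1.78 and 6.76 ± 1.62. The transcriptional coactivator gene eya3 (LOC100049216) was at 11.9 ± 0.0579 and 15.5 ± 1.38 FPKM, short of the threshold over the key genes alone (limma adjusted p = 0.0811).

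The reproductive axis list shifted down, with 16 of 19 genes lower in LD, a median of -0.24 and camera adjusted p = 0.00248 (adjusted p = 0.75 with an estimated correlation). Only gnrh3, which encodes a gonadotropin-releasing hormone of the forebrain, passed over the list alone: it fell 1.48-fold, from 41.2 ± 3.2 to 27.5 ± 1.31 FPKM (limma adjusted p = 0.024 over the list and 0.564 over all genes). This call was lost without LD 1, without LD 2, without SD 2 and with limma run without a trend (limma adjusted p between 0.0133 and 0.186 over the alternatives), and the list's call was lost without SD 2 (camera adjusted p = 0.343).

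The circadian clock list shifted up, with 22 of 33 genes higher in LD, a median of 0.12 and camera adjusted p = 0.000924 (adjusted p = 0.75 with an estimated correlation). Both LD libraries lay above both SD libraries for 15 of these genes and below for 3. Adjusted over the list alone, 3 genes rose and none fell. The light-responsive period gene per2, on chromosome 13 at 31713989 to 31729405, rose 2.18-fold from 5.75 ± 1.01 to 13.6 ± 0.0623 FPKM (limma adjusted p = 0.011 over the list and 0.281 over all genes). A gene described as nfil3-like (LOC101161892), a repressor of clock output genes, rose from 8.17 ± 1.5 to 18.2 ± 3.73 FPKM, and a second per2 gene (LOC101161338) from 8.9 ± 0.322 to 12.4 ± 0.0285 (limma adjusted p = 0.0347 and 0.0411 over the list). Without SD 2 the list was not called (median 0.02, camera adjusted p = 0.095), and without LD 1 none of the 3 genes passed over the list (for per2, limma adjusted p = 0.109, range 0.00824 to 0.109). The second per2 was lost without each of the libraries in turn, with the replicate number as a block and with limma run without a trend, and the nfil3-like gene also without SD 2 and without a trend.

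Other clock genes among the key genes did not pass and are given as values. The more abundant nr1d1 gene (LOC101174341) stood at 71.4 ± 1.81 FPKM in SD and 69.2 ± 1.63 in LD and the other (LOC101173939) at 15 ± 2.74 and 16.6 ± 0.387. The nr1d2 genes were at 21.9 ± 3.11 and 28.7 ± 1.51 (LOC101163230) and at 13.9 ± 4.94 and 18.3 ± 0.372 (LOC101156434). Cryptochrome genes described as cry1 were at 36.5 ± 5.22 and 46.1 ± 0.624 (LOC101167667) and 72.7 ± 14 and 84.2 ± 13.2 (LOC101164536). Less abundant ones were at 1.33 ± 0.0869 and 1.95 ± 0.657 (LOC101160902) and 1.61 ± 0.427 and 2.15 ± 0.248 (LOC101174986). Those of tef were at 30.6 ± 0.138 and 35 ± 0.215 (LOC101159928), 67 ± 8.5 and 66.9 ± 1.27 (LOC101164258), and 29 ± 16.8 and 19.7 ± 0.721 (LOC101172818). The period gene per1 stood at 9.85 ± 0.375 and 10.1 ± 1.13 FPKM.

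Over the 43 key genes tested, 1 passed over all genes (somatotropin). The more abundant second tshb did not pass over the key genes alone (limma adjusted p = 0.453). The 5 that did were somatotropin, tshb (LOC105354380) and gnrh3, which fell, and per2 and the second per2, which rose (limma adjusted p = 6.18e-05, 0.00329, 0.0136, 0.0048 and 0.0321). The count was 3 without LD 1 and 10 without SD 1. Somatotropin, tshb and per2 passed over the key genes alone in all 13 alternatives.

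Immediate early genes, which neurons switch on within minutes of activity, shifted up: 24 of 26 were higher in LD, with a median of 0.23 and camera adjusted p = 4.12e-07 (adjusted p = 0.75 with an estimated correlation). None passed over the list alone. The 2 most abundant, junB (LOC101164062) and egr1, stood at 72.5 ± 7.89 and 85.7 ± 12 FPKM and at 40.6 ± 5.48 and 43.9 ± 5.7. The fos genes were at 8.93 ± 0.275 and 11.4 ± 3.58 (LOC101165186) and at 7.08 ± 0.104 and 8.92 ± 1.93 (LOC101167759), with LD 1 the highest library for both. Other egr1 genes stood at 19.8 ± 2.35 and 24.2 ± 3.1 (LOC101169519) and at 3.62 ± 0.133 and 4.94 ± 2 (LOC101160576).

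The list that joins heat shock and unfolded protein response genes also shifted up, with 25 of 34 genes higher, a median of 0.10 and camera adjusted p = 0.000924 (adjusted p = 0.75 with an estimated correlation). None passed over the list alone. The cold-inducible gene cirbp stood at 1450.2 ± 57.3 FPKM in SD and 1571 ± 49.3 in LD, and hsp90ab1 at 754 ± 57 and 803 ± 31.2. Members of the unfolded protein response, chosen after their values were seen, had log2 changes on both sides of 0, with -0.24 for hyou1, -0.05 for xbp1, 0.03 for atf4 and 0.15 for sdf2l1. That response was not tested alone. Sterol and fatty acid synthesis genes shifted up as a list (18 of 22 higher, median 0.16, camera adjusted p = 0.000924, adjusted p = 0.75 with an estimated correlation), with elovl6 at 48.2 ± 7.19 and 54.6 ± 1.14 FPKM and msmo1 at 32.3 ± 4.35 and 47 ± 8.59. The fatty acid synthase gene fasn, chosen after its values were seen, stood at 14.6 ± 8.32 and 14.2 ± 1.45. Fatty acid genes were not tested apart from sterol genes. The cell cycle list also shifted up (19 of 25 higher, median 0.18, camera adjusted p = 0.0143, adjusted p = 0.75 with an estimated correlation), with pcna at 25.5 ± 4.86 and 32.5 ± 5.59 FPKM and mcm7 at 10.9 ± 0.949 and 10.2 ± 0.732. Without SD 1 none of these 3 lists was called (camera adjusted p = 0.215, 0.308 and 0.523), and without LD 2 the sterol list (0.0827) and the cell cycle list (0.902, median -0.02) were not. The cell cycle list was also not called among genes with a mean of at least 5 FPKM (0.317).

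**Figure D3:**
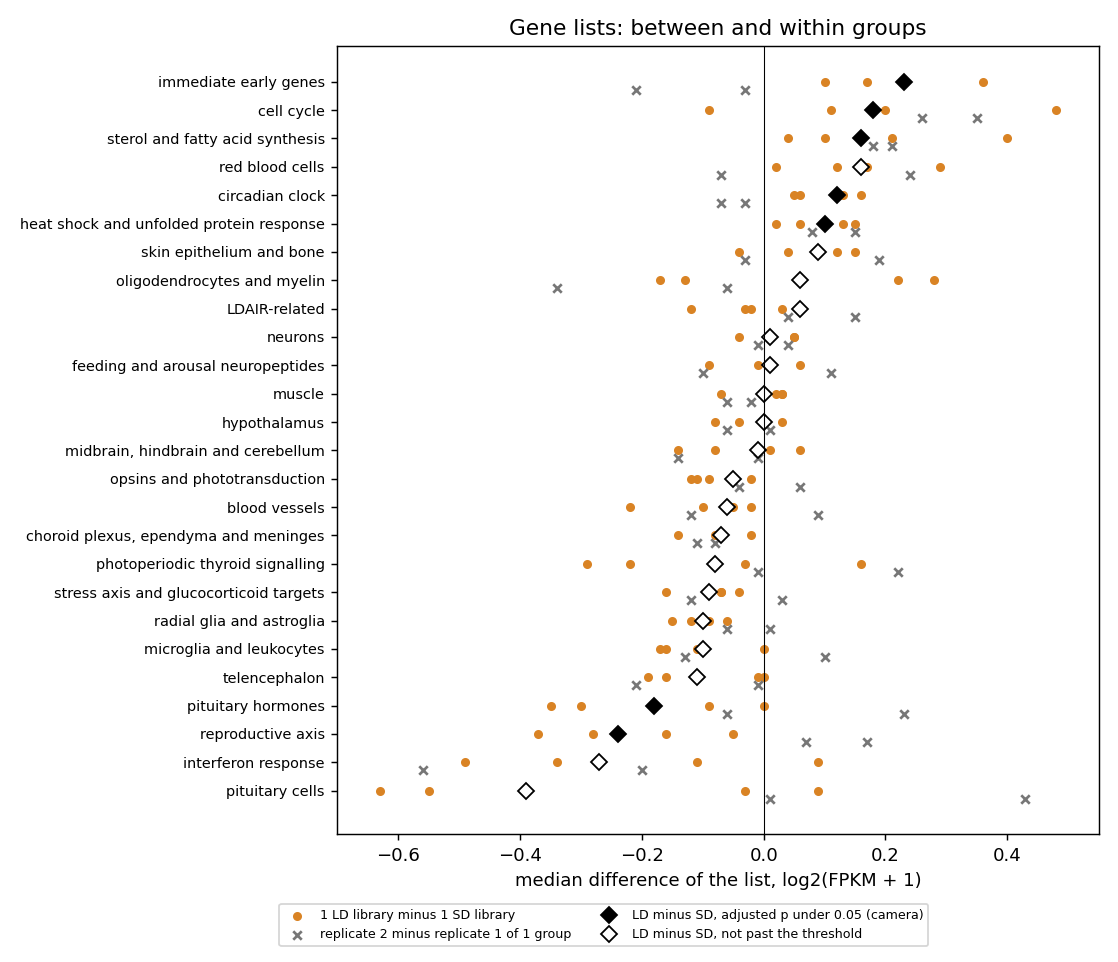
Median difference in log2(FPKM + 1) (x axis) for each of the 26 gene lists, as LD minus SD from the fit (diamonds, filled where called by camera), each LD library minus each SD library (orange points) and replicate 2 minus replicate 1 within a group (grey crosses). The immediate early list has the highest median at 0.23, and for cell cycle genes the differences within groups reach 0.35.

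The stress axis list was not called (9 of 24 genes higher, median -0.09, camera adjusted p = 0.273), but it was with features not summed (median -0.11, adjusted p = 0.048, against adjusted p = 0.75 with an estimated correlation and summed features). Its most abundant members were pomc, given above, and TSC22 domain family protein 3 (LOC101161414), a target of glucocorticoids, at 276 ± 5.09 FPKM in SD and 229 ± 16 in LD. The corticotropin-releasing hormone gene crh stood at 69.6 ± 8.76 and 68.9 ± 5.38, and a second gene of that description, LOC101166988, was listed at 0 in all 4 libraries. The glucocorticoid-responsive gene fkbp5 (LOC101157675) was at 74 and 27.2 FPKM in SD and 15.3 and 19.2 in LD, klf9 at 9.25 ± 4.72 and 6.26 ± 0.783, and a second klf9 (LOC101165098) at 4.9 ± 0.308 and 5.07 ± 0.386. Further genes described as pomc stood at 18 ± 6.31 and 17.8 ± 1.27 (LOC101164777) and at 1.65 ± 0.149 and 2.3 ± 0.92 (LOC101168338). Another gene described as per2, LOC101159817, was listed at 0 throughout.

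The LDAIR-related list, which holds genes matched by symbol or description on several chromosomes, was not called (4 of 7 higher, median 0.06, camera adjusted p = 0.729), and camera pointed up where fry pointed down. LDAIR itself, a long noncoding RNA of medaka, was not identified among the features and was not analysed here. Genes described as the lipid phosphatase lpin2 stood at 26.5 ± 2.05 and 29 ± 0.552 FPKM (LOC101161835), 2.9 ± 0.387 and 3.87 ± 2.24 (lpin2) and 1.41 ± 0.207 and 0.966 ± 0.116 (LOC101174419). The corticotropin-releasing factor receptor gene crhr2 (LOC101157488) stood at 5.19 ± 0.543 and 5.86 ± 0.925.

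The other lists of cell types and regions were not called by camera in the fit of all 4 libraries at the filter of 1 FPKM. Neuron markers (6 of 9 higher, median 0.01, adjusted p = 0.307) held snap25 at 871 ± 4.35 FPKM in SD and 866 ± 23.7 in LD and syt1 at 440.3 ± 17.7 and 459.6 ± 13.5. In the myelin list (21 of 28 higher, median 0.06, adjusted p = 0.307) the myelin proteolipid gene LOC101157800 was at 398 and 369 FPKM in SD and 606 and 325 in LD, and cd59 at 249 ± 18 and 327 ± 140.3. Without LD 1 the list median was -0.14 (adjusted p = 0.00429) and without LD 2 it was 0.28 (2.86e-08), so its direction rests on LD 1. With all 4 libraries it had adjusted p = 0.75 with an estimated correlation. Radial glia and astroglia (3 of 8 higher, median -0.10, mean 0.16, adjusted p = 0.74) held slc1a3, which rose over the list alone (limma adjusted p = 0.000349). Its median and camera pointed down, and its mean and fry up. Microglia and leukocytes (0 of 4 higher, median -0.10, adjusted p = 0.307) held cd74 at 134 ± 0.308 and 121 ± 8.13 and ptprc at 5.82 ± 0.986 and 4.85 ± 1.33. Blood vessel genes (5 of 11 higher, median -0.06, adjusted p = 0.31) held egfl7 at 25.5 ± 1.59 and 29.2 ± 9.15 and kdr at 21.9 ± 2.4 and 23.1 ± 5.28.

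Hemoglobin genes of red blood cells (3 of 3 higher, median 0.16, camera adjusted p = 0.279) stood at 1696 ± 281 and 1880.0 ± 61.8 FPKM (LOC101174997) and 7.71 ± 5.44 and 8.46 ± 0.342 (LOC101155030). The muscle list (7 of 14 higher, median 0.00, adjusted p = 0.684) held a parvalbumin gene (LOC101161860) at 153 ± 0.726 and 181 ± 9.62 and myoglobin (mb) at 77.9 and 20.3 FPKM in SD and 92.1 and 81.9 in LD. Skin epithelium and bone (3 of 5 higher, median 0.09, adjusted p = 0.494) held sparc at 132 ± 3.28 and 124 ± 20.3 and dsp at 7.29 ± 0.757 and 6.53 ± 0.108. Choroid plexus, ependyma and meninges (4 of 12 higher, median -0.07, adjusted p = 0.552) held aqp1 at 22.2 ± 6.32 and 29.4 ± 6.08 and igf2 at 11.7 ± 0.448 and 10.5 ± 0.483.

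For the dissected regions, telencephalon genes (4 of 13 higher, median -0.11, camera adjusted p = 0.307) held neurod2 at 52 ± 7.88 and 54.2 ± 5.18 FPKM and dlx1 at 52.6 ± 6.11 and 48.3 ± 0.235, and without SD 2 the list was called (median -0.09, adjusted p = 0.0286, against adjusted p = 0.75 with an estimated correlation and all 4 libraries). Hypothalamus genes (8 of 16 higher, median -0.00, adjusted p = 0.74) held oxt at 53.9 and 153 FPKM in SD and 270.3 and 60.8 in LD and isl1 at 30.4 ± 0.273 and 32 ± 2.42. Midbrain, hindbrain and cerebellum genes (5 of 10 higher, median -0.01, adjusted p = 0.517) held neurod1 at 59.2 ± 3.31 and 46.7 ± 4.81 and ca8 at 60.2 ± 4.45 and 48.4 ± 3.49. Feeding and arousal neuropeptides (19 of 34 higher, median 0.01, adjusted p = 0.838, with fry pointing down) held the melanin-concentrating hormone gene LOC101161984 at 893 ± 136 and 862 ± 10.7 and cck at 194 ± 10.3 and 231 ± 37.9. Opsins and phototransduction (7 of 19 higher, median -0.05, adjusted p = 0.338) had as its most abundant members 2 transducin-like enhancer genes, which are transcriptional corepressors and not part of phototransduction: LOC101157442 at 48.8 ± 1.26 and 45.5 ± 2.06 and LOC100049394 at 20.8 ± 2.92 and 19.6 ± 0.102. Interferon response genes (0 of 9 higher, median -0.27, adjusted p = 0.0684) held cmpk2 at 10.6 ± 0.459 and 10.1 ± 1.79 and rsad2 at 7.84 ± 1.77 and 6.47 ± 2.36, and the median of SD 2 minus SD 1 was -0.56 on the log2 scale. Its median was -0.01 without SD 1 (camera adjusted p = 0.976) and -0.43 without SD 2 (0.000144). The list was also called without LD 1 (median -0.31, adjusted p = 0.00755) and with the replicate number as a block (0.0117), against adjusted p = 0.75 with an estimated correlation and all 4 libraries.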

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

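All alternatives but 2 were listed in advance; the run without list members matched by words alone and the run with the heat shock 70 kDa protein 1 genes as 1 member were chosen after seeing the data, and each gave 7 lists called. Count-based tests were not run since the values are FPKM, and camera was not run with robust variance. A lone library was assumed to vary like the other group. Fits without 1 library or with the block have fewer residual degrees of freedom, so a lost call alone does not show a changed effect. The cause of the differences below was not tested.

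The count of genes past the threshold, 2, was 1 with a pseudocount of 0.1, 0 with no filter, 0 with the replicate number as a block, 5 with limma without a trend, 7 with features not summed, 4 at an adjusted p under 0.1, and 0 to 2 when 1 library was left out. The unadjusted count was 1925 with no filter, 1168 with the block and 849 to 1301 with a library left out. Same-numbered libraries did not deviate together (correlation over genes 0.02). Of the 2 genes called without LD 1 and the 2 called without SD 2, 0 were among the 2 reported. Of the key genes, 1 passed, and 0 did with no filter, with the block, with limma without a trend and with a library left out. Of the named genes, 2 passed: 1 with a pseudocount of 0.1, 0 with no filter, 0 with the block and 0 with a library left out. The 7 lists called became 0 with an estimated correlation and 0 with fry in 1 direction. In these 7 lists the estimated inter-gene correlation ran from 0.04 (clock) to 0.44 (cell cycle), above the preset 0.01. Where genes of a list correlate more than the preset, its camera p-value at the preset is too small. Fry for a change in either direction called 6 lists: radial glia (adjusted p = 0.0031), pituitary hormones (0.00945), hypothalamus (0.0112), pituitary cells (0.028), the clock (0.0396) and midbrain and hindbrain (0.0396). Immediate early genes were called in the 14 alternatives that used camera with the preset correlation, and not with an estimated correlation (adjusted p = 0.75) or by fry (0.543).

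Directions that turned were those of LOC101164777 with features not summed (-0.00), crh with median-ratio scaling (0.00) and LOC101164258 with quantile normalization (-0.00). For lists, camera's direction turned for feeding neuropeptides with no filter (median -0.00), a mean of at least 5 FPKM (-0.01), quantile normalization (0.01) and without members matched by words alone (0.01), for radial glia with limma without a trend (-0.10), and for muscle with no filter (-0.01). The list median turned for midbrain and hindbrain with median-ratio scaling (0.01) and quantile normalization (0.02), and for skin and bone with a mean of at least 5 FPKM (-0.01). Scaling moved the median of all genes by 0.01.

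With a library left out, the log2 change turned for the second tshb LOC101171658 (-2.02 to 0.37), cga (-1.16 to 0.07), dio3 (-0.15 to 0.36), fshb (-0.43 to 0.14), prl (-0.04 to 1.41), LOC101164777 (-0.32 to 0.37), LOC101168338 (-0.00 to 0.58), crh (-0.14 to 0.12), lpin2 (-0.24 to 0.73), per1 (-0.08 to 0.13), LOC101173939 (-0.03 to 0.32), LOC101164258 (-0.12 to 0.13), LOC101172818 (-1.02 to 0.19), LOC101165098 (-0.02 to 0.11), klf9 (-0.91 to 0.07), LOC101165186 (-0.00 to 0.59), egr1 (-0.03 to 0.24) and LOC101160576 (-0.03 to 0.67). The list median or camera's direction turned for the cell cycle list (-0.02 to 0.33), photoperiodic thyroid signalling (-0.22 to 0.09), feeding neuropeptides (-0.05 to 0.04), interferon response (-0.43 to -0.01), oligodendrocytes (-0.14 to 0.28), radial glia (-0.12 to -0.09), skin and bone (-0.09 to 0.24), choroid plexus (-0.09 to -0.01), telencephalon (-0.11 to -0.00), hypothalamus (-0.10 to 0.06), midbrain and hindbrain (-0.11 to 0.03), muscle (-0.03 to 0.06), neurons (-0.01 to 0.03) and LDAIR-related genes (-0.02 to 0.05).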

Other observations

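All tests of explanations in this part were chosen after the results were seen, and the genes of the next paragraph were chosen after their values were seen.

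Prolactin-1 (LOC101172582), which the key gene match had missed, was the most abundant hormone gene looked at, with 3899.6 and 3743.0 FPKM in SD and 1825.0 and 3536.0 in LD. It did not pass the threshold (limma adjusted p = 0.801). Of genes of glia and barriers, the sodium bicarbonate cotransporter 1 gene (LOC101158338) stood at 258 ± 5.27 FPKM in SD and 175 ± 7.74 in LD, and the gap junction alpha-1 gene (LOC101170140) at 182 ± 8.6 and 121 ± 8.58, neither past the threshold (limma adjusted p = 0.281 and 0.442). Neuritin (nrn1), a gene induced by neuronal activity, was at 35.2 ± 0.48 and 49.9 ± 1.91 FPKM, and a PACAP receptor gene (LOC101168197) at 16.8 ± 1.14 and 11.7 ± 0.18. Neither passed the threshold (limma adjusted p = 0.45 and 0.62). Pairs of related genes named by the rule had values on the same side: arrdc3 and LOC101167126 lower in LD, and lonrf2 and lonrf3 higher. These pairs were noticed among genes picked by rank in each direction, so their agreement is no test. Other pairs were not searched.

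Somatotropin fell over all genes, and tshb (LOC105354380) fell over the lists and key genes alone (limma adjusted p = 0.188 over all genes). The more abundant second tshb did not pass. Somatolactin had lower values in LD without passing (limma adjusted p = 0.0519 over the list). A smaller share of pituitary tissue in the LD libraries, lowering all its hormones alike, is argued against as the whole cause. The 95% interval of the log2 change lay above the -1.73 of somatotropin for 5 of 6 other pituitary hormone genes. These were pomc, lhb, fshb, cga and prolactin-1, but not the second tshb. The -1.73 was taken without its own error, and somatotropin had the smallest p of all genes, which favours a gap. The lower bound of cga (-1.57) lay close to it and that of pomc (-0.52) far above it. An uneven loss of pituitary cells was not tested. A part of the lower values could still come from dissection. A change in hormones that depend on the transcription factor pou1f1 was tested on somatolactin, the second tshb and prolactin-1 against pomc, lhb, fshb and cga, with medians of -0.80 and -0.38 and an exact one-sided permutation p = 0.0571 over 35 arrangements (smallest possible 0.0286). Somatolactin is 1 of the genes to be explained, and cga, the shared alpha subunit, is also part of thyrotropin. The permutation treats genes measured in the same libraries as replicates. That test therefore decides nothing, and both this explanation and an effect of day length stay open.

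For the 7 lists called, differences between libraries of 1 group cannot be told apart from the transfer to long days as the origin of the shifts. Only LD fish were moved and tissue was taken at 16 h only. A response to the transfer itself, or to the light around the time of collection, therefore cannot be told apart from one to day length. In 4 of 7 lists the median shift within a group was at least as large as that between groups: heat shock (0.15 against 0.10), sterol synthesis (0.21 against 0.16), cell cycle (0.35 against 0.18) and pituitary hormones (0.23 against 0.18). It was smaller for the clock (0.07 against 0.12), reproductive (0.17 against 0.24) and immediate early lists (0.21 against 0.23). The shift within a group is the larger of those of the 2 groups and compares single libraries. That between groups compares means of 2 libraries, so the former is expected to be larger where the spread is equal. With 2 libraries per group these shifts were not tested against each other.

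Features listed at 0 in both libraries of 1 group and at 1 FPKM or more in both of the other numbered 16, of which 10 were at 0 in SD and 6 in LD. Splits with 1 SD and 1 LD library on each side gave 12 and 10, so most such features are consistent with differences between fish or libraries not tied to day length. Reads shared with an overlapping feature stay open, since 62.5% of the 16 overlap another feature, against 59.5% of all tested. MEDAKA053081 is among the 16, and for it no explanation was tested alone.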
